A study of Mus musculus with 5 samples.

How the data were processed

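Macrophages of male C57BL6/j mice were measured by droplet single-cell RNA sequencing with the 10x Genomics Chromium 3′ kit, in which each transcript carries a unique molecular identifier (UMI) and is counted near its 3′ end. There were 5 libraries in 5 groups, 1 library per group: macrophages sorted from the visceral adipose tissue of lean mice and of obese mice (adipose tissue macrophages, ATM), and bone marrow-derived macrophages (BMDM) left unstimulated (M0), stimulated with lipopolysaccharide (LPS) and interferon gamma (M1) or stimulated with interleukins IL-4 and IL-13 (M2). Groups were taken from the sample titles.

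The deposited files hold raw UMI counts per gene and cell barcode, as sparse matrices with their gene and barcode lists, 1 set per library. The submitters' processing notes name Cell Ranger 1.3, bcl2fastq 2.17.1.14 and the mouse genome build mm10, with no role or setting for any of them. The annotation release and the rule by which barcodes were kept as cells are not given in the sources used here. The deposited counts carry 27998 gene identifiers in every library. The lowest total was 1713 UMIs for a barcode of the lean ATM library, 2858 in obese ATM, 3623 in M0, 3845 in M1 and 3223 in M2, so barcodes below these totals, which would measure free RNA directly, were not analysed here. Coordinates are those of GRCm38 (mm10) in GENCODE mouse release 21, in which 27645 of the identifiers were found; symbols are those of the files, and Irg1 is called Acod1 in that release. An identifier that duplicates the symbol Itgam was not used for it. Counting near the 3′ end cannot fully part near-identical genes, so values of single members are uncertain for Hspa1a and Hspa1b, the Cd209 genes, the ribonuclease 2 family with Rnase2a, the guanylate-binding proteins, Ifi205, Serpina3g, the haemoglobin genes and the H2 genes. Overlapping genes have the same limit.

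Cells were kept with at least 200 detected genes and at most 10% of UMIs from mitochondrial genes. This left 1705 of 1710 barcodes of lean ATM, 1758 of 1758 of obese ATM, 6869 of 6979 of M0, 4561 of 4736 of M1 and 6232 of 6391 of M2. Scrublet, run in scanpy 1.11.5 on each library, called 2 doublets in lean ATM, 0 in obese ATM, 1 in M0, 0 in M1 and 1 in M2. A share this low was taken to mean that the caller did not work here, which was not tested. No cell was left out as a doublet, so doublets may remain among the kept cells in unknown number.

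Cells are not replicates. UMI counts were therefore summed over the kept cells of each library, or of its macrophage-like cells, and given as counts per 1000000 UMIs (CPM) of that sum. With 1 library per group there is no replicate check and no test was made between groups: each ratio compares these libraries, and its exact 95% conditional interval (a binomial interval on the split of the summed UMIs) covers counting error only. Shares of cells carry exact 95% Clopper-Pearson intervals with the same limit, and a count of 0 was given the upper limit of 3 counts. A gene was counted as higher or lower at a ratio of at least 2 with at least 10 CPM in the library where it was higher. Against 0 UMIs the ratio was taken against a floor of 3 UMIs in that sum and is a lower bound, written as at least N-fold; list medians take such genes at that bound. A gene without that level, or at or under the floor in both libraries, was not tested. These are counts by a fixed rule of size.

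The comparisons were M1 over M0, M2 over M0, M1 over M2, obese over lean ATM over all kept cells, and obese over lean ATM over macrophage-like cells. Before the data were examined, 16 gene lists, 26 classes of cell type markers, the rule for naming genes, the main settings and the alternatives to try were fixed. The lists cover classical activation, interferon response, alternative activation, MHC class II, MHC class I, cholesterol synthesis, glycolysis, oxidative phosphorylation, cell cycle, lipid-associated macrophage, lysosome, resident macrophage, monocyte, inflammatory cytokine, immediate early and stress, and fatty acid oxidation and PPAR genes; several lists share members. A list is described by the median log2 ratio over its tested members and by the percentile of that median among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Genes were named as follows: per comparison, the 10 largest and the 10 smallest ratios among genes of at least 50 CPM, ranked on (CPM + 1)/(CPM + 1); per list, the 4 members with the highest CPM and every member that differed 4-fold or more; and Nos2, Il12b, Arg1, Retnla, Chil3, Mrc1, Cd86, Adgre1, Csf1r, Cd68, Itgam, Ptprc and Xist as checks in every library. The text names most of the ranked genes, examples from the lists, and the members that make up a count of 5 or fewer, which were picked after their values were seen. Single-gene results of some list members are not reported here.

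The 2 ATM libraries were clustered together: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2). Each BMDM library was clustered alone at resolution 0.5. The marker score of a class in a cluster is the mean over its markers of log2 of the cluster's CPM plus 10 over the mean CPM of the other clusters plus 10. A cluster was called after the class with the highest score when that score was at least 1 and at least 3 markers reached 50 CPM at 2-fold over the other clusters, with 2 or more of them seen in at least 50% of its cells; a cluster where a class of another lineage also met the first of these bounds, at 50% or more of the best score, was called mixed. A cluster without such a class was macrophage-like when at least 8 of the 11 macrophage markers reached 50 CPM and its macrophage score was not below its monocyte score. These bounds were set after the data had been seen. A cluster whose best class was proliferating cell took that name without the mixed check. Cluster 18 (8 lean and 14 obese cells) was one, at a score of 3.10 with cDC1 second at 2.46. Clusters 0 and 3 are macrophage-like by the marker level alone, and cluster 10 stayed unnamed. No cluster of a compared class had more markers of another class than of its own among its 10 leading genes; clusters 0 and 4 had none of either.

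To compare shares of cells with a UMI of a gene across depths, each cell was thinned at random to 1500 UMIs; no cell was too shallow for this. Classical and alternative activation scores are, per cell at that depth, the mean log-normalised value of a list, and the difference of the 2 was compared between libraries. Signatures of M1 and M2 were the 100 genes of at least 50 CPM in that library with the largest value of the smaller of 2 ratios, over M0 and over the other stimulated library; they were then read in the ATM libraries. Their intervals come from 1000 Poisson draws of the counts.

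Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternative scalings came from edgeR 4.0.16 (trimmed mean of M values, TMM) and DESeq2 1.42.0 (size factors) in R 4.3.3. They were run for each comparison on the counts summed over the kept cells, or over the macrophage-like cells, of its libraries. The code for ratios, counts and list percentiles was tested on simulated counts in which 200 genes were changed. Clustering, cell naming, thinning, scores, signatures and the tests of explanations were not tested in this way. Both simulated sums came from the same library's profile with Poisson error only, so unchanged genes could hardly reach 2-fold. In each of the M1 over M0, M2 over M0, M1 over M2 and all-cell obese over lean simulations, 100% of genes changed 4-fold were counted (6519, 6584, 6152 and 7491 genes run), 0% of genes changed 1.5-fold, which lies under the bound of 2, and 0 unchanged genes.

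Alternatives set beforehand were stricter cell filters (500 genes, 5% mitochondrial UMIs), every deposited barcode, removal of Scrublet calls, a floor of 50 CPM or none, TMM and DESeq2 factors, a total without genes above 1% of UMIs, the mean of per-cell CPM, signatures of 50 or 200 genes or from genes of at least 10 CPM, thinning to 1000 or 3000 UMIs or none, Leiden resolutions of 0.5 and 2, and scores without the member with the highest CPM. Added after the data had been seen were removal of the 5% of cells with the highest Scrublet scores, the all-cell ATM comparison without fibroblast-like, B cell-like and mixed clusters, macrophage-like cells named by marker score alone, and the score alternatives for obese against lean ATM.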

Results

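Macrophages of male C57BL6/j mice were profiled in 5 single-cell libraries, 1 per group. The lean mice ate chow with 18% of calories from fat and the obese mice a high-fat diet with 60%, both for 12 weeks, and all mice were 17 to 18 weeks old. From visceral fat, cells carrying CD45.2, CD11b and F4/80, surface proteins of leukocytes, myeloid cells and macrophages, were sorted to give the lean and obese adipose tissue macrophage (ATM) libraries. Bone marrow-derived macrophages (BMDM) of chow-fed mice were grown for 7 days in medium conditioned by L-929 cells, a fibroblast line that secretes macrophage growth factor. They were left unstimulated (M0), given LPS at 100 ng/mL with interferon gamma at 50 ng/mL (M1), or given IL-4 and IL-13 at 20 ng/mL each (M2). The time under stimulus and the number of mice per library are not in the sample labels. The kept cells held 11226611 UMIs in lean ATM (1705 cells, median 5407 UMIs and 1868 genes per cell) and 20521207 in obese ATM (1758 cells, 9838.5 and 2754). The cultured libraries held 90712006 UMIs in M0 (6869 cells, 11654 and 2650.0), 77685589 in M1 (4561 cells, 16379 and 3079) and 85856184 in M2 (6232 cells, 13196.5 and 2744). With 1 library per group no difference below has a replicate check. Values in parentheses after a ratio are its exact 95% conditional interval, which covers counting error only.

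All libraries carried macrophage transcripts. Adgre1, which encodes F4/80, stood at 231 counts per 1000000 UMIs (CPM) in lean ATM, 565 in obese ATM, 362 in M0, 375 in M1 and 279.6 in M2. In the same order Cd68, a lysosomal membrane protein, stood at 583, 1273, 1865, 906 and 2096 CPM, and Csf1r, the receptor of macrophage growth factor, at 438, 534, 422, 105 and 234. Itgam, which encodes CD11b, stood at 159.7, 155, 111, 39.9 and 124 CPM, and Ptprc, which encodes CD45, at 357, 368, 112, 107 and 116. Xist, the X-inactivation RNA of female cells, had 2 UMIs in M0, 1 in M2 and 0 in the other libraries, and the Y-linked Ddx3y stood between 21.7 CPM in M1 and 65.2 CPM in lean ATM.

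Each stimulus left its hallmark genes in its own library. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254, plus strand), stood at 338 CPM in M1 and 0.419 CPM in M2, with 1 UMI each in M0, lean ATM and obese ATM. At 1500 UMIs per cell, 36.9% (Clopper-Pearson 35.5 to 38.3) of M1 cells held a Nos2 UMI, 89.9% without thinning, against 0.0321% of M2 cells and 0 of 6869 M0 cells, which allows up to 0.0437%. Arg1, arginase 1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand), stood at 2182 CPM in M2 and held a UMI in 77.0% (75.9 to 78.03) of M2 cells at 1500 UMIs, 97.7% without thinning. The shares were 0.611% in M0, 0.132% in M1, 2.46% in lean ATM and 0.910% in obese ATM. Il12b, an interleukin-12 subunit, reached 6.72 CPM in M1 and 3.12 CPM or less in the other libraries, and at 1500 UMIs 0.439% of M1 cells held a UMI of it. Cd86, a co-stimulatory ligand, stood at 265 CPM in M1, 9.21 in M0, 6.36 in M2, 72.8 in lean ATM and 54.7 in obese ATM. Chil3, a chitinase-like protein, stood at 559 CPM in M2, 83.6 in lean ATM and 154 in obese ATM, and Mrc1, the mannose receptor CD206, at 364 in M2, 153 in M0, 2.19 in M1, 193 in lean ATM and 164 in obese ATM.

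Retnla, a secreted protein induced by IL-4 (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand), stood at 8384 CPM in lean ATM, 3579 in M2 and 632 in obese ATM. At 1500 UMIs it was seen in 81.0% of lean and 14.9% of obese ATM cells, 97.4% and 49.5% without thinning. Free RNA can give UMIs in cells that lack a gene. Doublets of B cells with macrophages could also do so and were not tested. In lean B cell-like cells, which should lack Retnla, 65.0% (26 of 40 cells, median 4030 UMIs before thinning) held a UMI at that depth. The share was 90.8% in lean macrophage-like cells (669 of 737, median 6168). In obese ATM the shares were 10.0% of B cell-like cells (1 of 10, median 6299.5) and 19.1% of macrophage-like cells (189 of 990, median 12021). Retnla in lean macrophage-like cells stood at 14219 CPM against 1162 CPM in lean B cell-like cells.

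**Figure D1:**
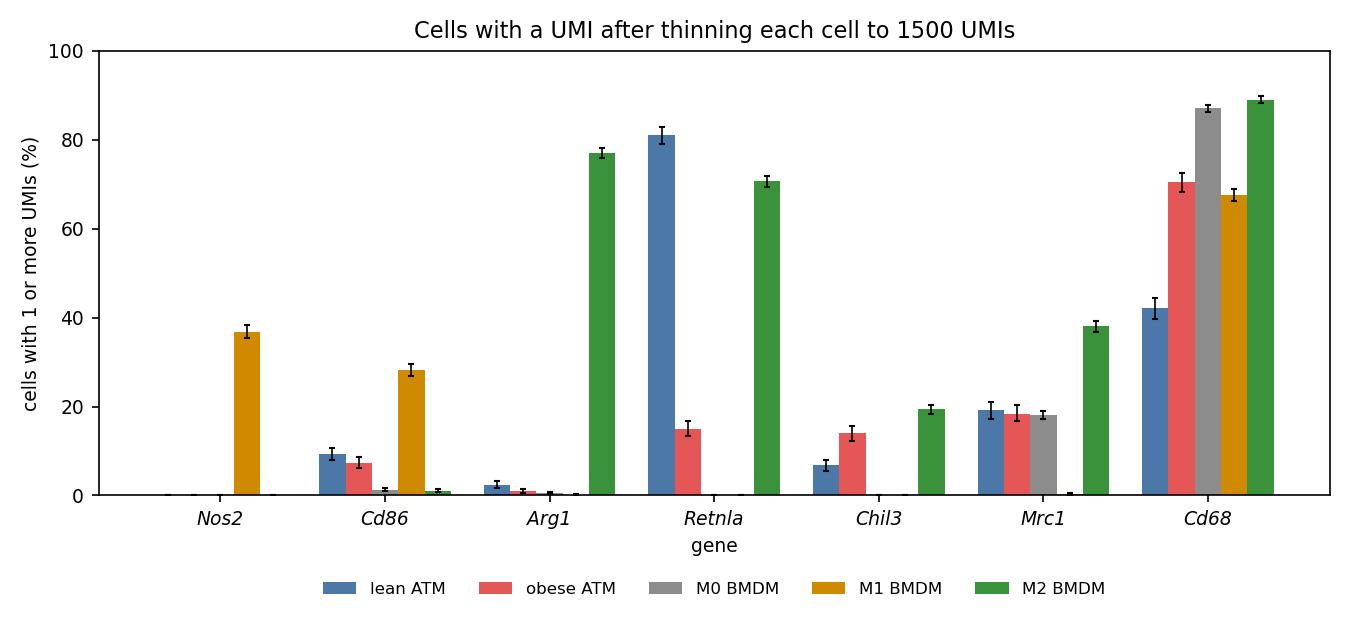
Bars give the percent of cells with 1 or more UMIs of a gene (vertical axis, percent of kept cells) after each cell was thinned to 1500 UMIs, for 7 genes (horizontal axis) in the lean ATM, obese ATM, M0, M1 and M2 libraries, with exact 95% Clopper-Pearson intervals that cover counting error only. Nos2 reaches 36.9% in M1 against 0.0321% in M2, and Arg1 77.0% in M2, while Retnla reaches 70.6% in M2, 81.0% in lean ATM, where 65.0% of B cell-like cells, which should lack it, also held a UMI, and 14.9% in obese ATM.

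The M1 library was set against M0 to ask which transcripts LPS and interferon gamma bring up or down. All 20 interferon-response, 7 MHC class II and 11 MHC class I genes tested were higher. Ccl5, a chemokine for T cells and monocytes (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, minus strand) and among the 10 largest ratios, stood at 31521 against 12.0 CPM (2626-fold higher, 2474 to 2789). Saa3, an acute-phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), stood at 2843 against 0.959 CPM (2964-fold higher, 2403 to 3701). Cell-cycle genes were lower in 16 of 18 members, lipid-associated macrophage genes in 16 of 23 and resident macrophage genes in 9 of 11. Mmp12, macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, plus strand) and among the 10 smallest ratios, stood at 3.57 against 1439 CPM (404-fold lower, 359 to 456). By the size rule 725 of 6984 genes were higher and 1329 lower in M1, and 361 and 423 of them differed 4-fold or more.

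Of 16 tested classical activation genes, 14 were at least 2-fold higher and 2 lower, with a median log2 ratio of 6.80, at percentile 100 of random lists (95% of random medians lay from -0.67 to 0.38). With TMM and DESeq2 factors 17 members were tested, with medians of 7.89 and 7.94, and the same 16 stood at 7.14 and 7.19. Cxcl9, an interferon gamma-induced chemokine (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079, minus strand), stood at 676 CPM against 0 UMIs (at least 20435-fold higher). Cxcl10, a ligand of the same receptor, stood at 939 against 0.739 CPM (1271-fold higher, 1001 to 1641), and Irg1, the enzyme that makes itaconate, at 789 against 0.165 CPM (4768-fold higher). Nos2 stood at 338 against 0.0110 CPM (30633-fold higher, 5498 to 1.21e+06), an interval this wide because M0 held 1 UMI. The lower members were the chemokines Ccl3, at 36.2 against 244 CPM (6.74-fold lower, 6.48 to 7.01), and Ccl4, at 83.9 against 391 CPM (4.65-fold lower, 4.53 to 4.78). The inflammatory cytokine list, which shares several of these genes, had 9 of 12 members higher and 2 lower, with a median of 2.87 (percentile 100). Tnf stood at 171 against 8.47 CPM (20.2-fold higher, 18.7 to 21.7), Il1b at 34.1 against 2.54 CPM (13.4-fold higher), Ptgs2, the inducible cyclooxygenase, at 129 against 0.165 CPM (782-fold higher), and Ccl2, a monocyte chemokine, at 901 against 307 CPM (2.93-fold higher).

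All 20 interferon-response genes were higher, with a median of 6.58 (percentile 100). Among them were Ly6a, the surface protein Sca-1, at 3477 against 7.13 CPM (488-fold higher, 451 to 527), and Isg15, a ubiquitin-like modifier, at 2561 against 26.3 CPM (97.4-fold higher). Others were Gbp2, a guanylate-binding protein, at 2099 against 11.04 CPM (190.2-fold higher), and Irf7, a transcription factor of the interferon pathway, at 1929.9 against 20.6 CPM (93.7-fold higher). Further genes among the 10 largest ratios were Ubd, a ubiquitin-like protein, at 611 CPM against 0 UMIs (at least 18469-fold higher), and Serpina3g, a protease inhibitor, at 639 against 0.0661 CPM (9656-fold higher). The interferon-inducible GTPases Gbp4, at 744 against 0.430 CPM (1731-fold higher), and Iigp1, at 703 against 0.474 CPM (1483-fold higher), were also among them. Both antigen-presentation lists were higher throughout: 7 of 7 MHC class II genes (median 3.42, percentile 99.99) and 11 of 11 MHC class I genes (median 2.34, percentile 100). H2-Aa stood at 1779.9 against 166 CPM (10.7-fold higher, 10.5 to 10.9) and Cd74, the invariant chain, at 7199.8 against 562 CPM (12.8-fold higher). B2m, beta-2 microglobulin, stood at 17047 against 4077 CPM (4.18-fold higher) and Tap1, a peptide transporter, at 326 against 28.2 CPM (11.6-fold higher).

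Cell-cycle genes were lower, 16 of 18 members, with a median of -3.74 (percentile 0). Mki67, a proliferation marker, stood at 1.54 against 22.4 CPM (14.5-fold lower, 12.0 to 17.6) and Ccnb2, a mitotic cyclin, at 0 UMIs against 22.6 CPM (at least 586-fold lower). The mitotic Ube2c was at 0.0901 against 58.3 CPM (647-fold lower) and the tubulin-binding Stmn1 at 2.55 against 208 CPM (81.5-fold lower). Clustering of each library found a proliferating cluster of 8.44% (7.80 to 9.13) of M0 cells and none in M1. Of lipid-associated macrophage genes 16 of 23 were lower and 2, Npc2 and Acp5, higher (median -1.62, percentile 0). Spp1, osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand), stood at 169 against 7345 CPM (43.4-fold lower, 42.6 to 44.1) and the lipid receptor Trem2 at 503 against 2076 CPM (4.13-fold lower). The fatty acid-binding Fabp4 was at 18.8 against 242 CPM (12.8-fold lower) and Atp6v0d2, a proton pump subunit, at 19.1 against 504 CPM (26.4-fold lower). Resident macrophage genes were lower in 9 of 11 members (median -3.77, percentile 0). Mrc1 stood at 2.19 against 153 CPM (69.8-fold lower, 60.0 to 81.7) and Sepp1, the plasma selenoprotein, at 131 against 3049 CPM (23.3-fold lower). The chemokine Ccl8 was higher, at 1028 against 7.58 CPM (136-fold higher). Other genes among the 10 smallest ratios were Fcrls, at 1.26 against 118 CPM (93.5-fold lower), and Ramp1, a calcitonin-family receptor subunit, at 0.515 against 71.1 CPM (138-fold lower). The list of 10 also held Pcp4l1, at 0.618 against 58.6 CPM (94.8-fold lower), and the chemokine Ccl6, at 60.1 against 1759 CPM (29.3-fold lower).

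Cholesterol synthesis genes were lower in 8 of 13 members (median -1.31, percentile 0.265), with Idi1 at 1.69 against 10.2 CPM (6.03-fold lower) and Hmgcs1 at 9.35 against 29.5 CPM (3.15-fold lower). The alternative activation list had 3 of 7 members lower, Mrc1, Clec10a and Egr2, and 2 higher, Il4ra and Klf4 (median -0.99, percentile 2.01). Its sign depends on the floor: with a floor of 50 CPM the median was 1.65. The immediate early and stress list had 4 of 14 members higher, Dusp1, Hspa1a, Klf6 and Socs3, and Btg2 lower (median 0.72, percentile 99.9). Of 8 monocyte genes 3 were higher, Plac8 and Ms4a4c among them, and 3 lower, Ccr2, S100a4 and Napsa (median 0.11, percentile 85.8, and -0.02 with no floor). Plac8 stood at 121 against 1.995 CPM (60.5-fold higher) and S100a4 at 38.02 against 432 CPM (11.4-fold lower). Medians near 0 were found for glycolysis (0.01, percentile 65.2, Pfkp and Pfkfb3 higher) and oxidative phosphorylation (0.03, percentile 69.4, Cox5a higher). The median was -0.05 for lysosome genes (percentile 60.5), which turned to 0.30 with TMM and 0.34 with DESeq2 factors, and -0.31 for fatty acid oxidation and PPAR genes (percentile 39.6), which turned to 0.10 with TMM and 0.14 with DESeq2 factors, or to 0.03 and 0.08 over the same members.

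Scaling shifts every BMDM ratio. With TMM or DESeq2 factors in place of total UMIs, the median log2 ratio of all tested genes moved up by 0.35 or 0.39 for M1 over M0. It moved by 0.17 or 0.18 for M2 over M0 and 0.23 or 0.23 for M1 over M2. The counts of higher and lower genes became 1126 and 827 or 1190.0 and 773 for M1 over M0 (35.3% higher with total UMIs, 57.7% and 60.6% with these factors). They became 341 and 198 or 343 and 195 for M2 over M0 (47.8%, 63.3% and 63.8%) and 1214 and 914 or 1211 and 915 for M1 over M2 (43.6%, 57.0% and 57.0%). With a total that leaves out genes above 1% of UMIs the shifts were 0.15, -0.01 and 0.18. A floor of 50 CPM lowered, and no floor raised, the counts of higher and of lower genes in each comparison, ATM included. All values given are on total UMIs, and a log2 ratio smaller than these shifts has no firm direction.

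M2 was set against M0 to ask the same of IL-4 and IL-13. Fewer genes differed: 258 of 6740 were higher and 282 lower, 90 and 48 of them 4-fold or more. Alternative activation genes were higher in 15 of 17 members. Retnla stood at 3579 against 0.0220 CPM (1.62e+05-fold higher, 44936 to 1.34e+06), with 2 UMIs in M0, and Arg1 at 2182 against 5.58 CPM (391-fold higher, 358 to 428). Cell-cycle genes were lower in 16 of 18 members.

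The alternative activation list had 15 of 17 members at least 2-fold higher and 0 lower, with a median of 5.10 (percentile 100, random medians from -0.29 to 0.08). Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564, minus strand) stood at 559 against 0.209 CPM (2668-fold higher, 1708 to 4432) and Mgl2, a galactose-type lectin (ENSMUSG00000040950, chromosome 11, 70130329 to 70137550, plus strand), at 596 against 2.95 CPM (202-fold higher, 179 to 228). The chemokines Ccl24, at 82.0 against 0.992 CPM (82.6-fold higher), Ccl22, at 33.2 against 2.59 CPM (12.8-fold higher), and Ccl17, at 34.1 against 0.0331 CPM (1029.8-fold higher, 352 to 4996) with 3 UMIs in M0, were also higher. So were Pdcd1lg2, the checkpoint ligand PD-L2, at 18.4 against 0.220 CPM (83.6-fold higher), and Cish, an inhibitor of cytokine signalling, at 48.4 against 1.11 CPM (43.4-fold higher). Flt1, a VEGF receptor, stood at 89.5 against 2.60 CPM (34.4-fold higher) and Mrc1 at 364 against 153 CPM (2.38-fold higher, 2.33 to 2.43). Other large ratios belonged to Rnase2a, an eosinophil-type ribonuclease, at 455 against 0.0220 CPM (20636-fold higher, 5712 to 1.70e+05) with 2 UMIs in M0, and Rbp4, a retinol carrier, at 185 against 0.132 CPM (1402-fold higher). Slc7a2, a transporter of arginine, stood at 108 against 0.430 CPM (252-fold higher), the membrane protein Tmem26 at 107 against 0.0992 CPM (1079-fold higher) and the claudin Cldn11 at 64.6 against 0.121 CPM (533-fold higher).

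The lipid-associated macrophage list had 3 of 23 members higher and 2 lower (median 0.30, percentile 99.98). Higher were Itgax, which encodes CD11c, at 215 against 26.5 CPM (8.13-fold higher, 7.80 to 8.49), the phosphatase Acp5, at 56.4 against 6.83 CPM (8.26-fold higher), and Ctsk, cathepsin K, at 42.0 against 10.0 CPM (4.19-fold higher). Lower were Spp1, at 2392 against 7345 CPM (3.07-fold lower, 3.06 to 3.09), and Apoe, at 596 against 2107 CPM (3.54-fold lower). Pparg, the nuclear receptor of lipid metabolism, stood at 70.7 against 30.4 CPM (2.33-fold higher). Monocyte-list members also parted (median 0.33, percentile 98.9). Chil3, Fn1, fibronectin, at 206 against 5.68 CPM (36.2-fold higher, 33.2 to 39.6), and F10, at 123 against 14.8 CPM (8.30-fold higher), were higher. Ccr2, at 7.58 against 28.1 CPM (3.71-fold lower), and Ifitm6, at 3.25 against 18.0 CPM (5.53-fold lower), were lower. This median turned to -0.75 with no floor on CPM. MHC class II genes had a median of 0.52 (percentile 99.4) with Cd74 alone past 2-fold, at 1389 against 562 CPM (2.47-fold higher).

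On the lower side, cell-cycle genes had 16 of 18 members lower (median -1.54, percentile 0), with Mki67 at 7.73 against 22.4 CPM (2.89-fold lower, 2.65 to 3.16) and Stmn1 at 70.9 against 208 CPM (2.93-fold lower). A proliferating cluster held 2.84% (2.44 to 3.28) of M2 cells against 8.44% of M0 cells. Resident macrophage genes had 5 of 12 members lower, Folr2, F13a1, Gas6, Sepp1 and Stab1, and 4 higher, Mrc1, Ccl8, Clec10a and Mgl2 (median -0.53, percentile 0.010). Folr2, a folate receptor, stood at 45.8 against 199 CPM (4.34-fold lower, 4.19 to 4.49) and Ccl8 at 211 against 7.58 CPM (27.9-fold higher). The inflammatory cytokine list had 4 of 7 members lower, Ccl2, Ccl3, Ccl4 and Nlrp3 (median -1.33, percentile 0.010), with Ccl3 at 56.5 against 244 CPM (4.32-fold lower). The 10 smallest ratios included Ms4a6b, at 4.18 against 56.3 CPM (13.5-fold lower), and Slc40a1, the iron exporter ferroportin, at 11.4 against 136 CPM (11.9-fold lower). Igfbp4 stood at 8.01 against 97.6 CPM (12.2-fold lower) and C5ar1, the complement C5a receptor, at 34.5 against 281 CPM (8.13-fold lower). Hpgds, a prostaglandin D synthase, stood at 22.6 against 149 CPM (6.61-fold lower) and Fcgr1, the Fc receptor CD64, at 18.0 against 105 CPM (5.87-fold lower).

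Immediate early and stress genes had 2 of 12 members higher, Jun and Ier3 (median 0.56, percentile 100). The classical activation median was -0.72 over 4 members (percentile 0.410). Under other scaling 5 members passed the floor, with medians of 0.15 with TMM and 0.16 with DESeq2 factors, while the same 4 members stayed below 0, at -0.55 and -0.54. Interferon response (-0.14, percentile 52.9) turned to 0.03 with TMM and 0.04 with DESeq2 factors, and MHC class I (-0.10, percentile 30.4) to 0.07 with TMM and 0.08 with DESeq2 factors. Oxidative phosphorylation (-0.04, percentile 42.3) turned to 0.13 with TMM and 0.14 with DESeq2 factors, and fatty acid oxidation and PPAR genes (-0.04, percentile 84.6) to 0.13 with TMM and 0.14 with DESeq2 factors. Lysosome genes stood at 0.10 (percentile 95.9, Ctsz higher), cholesterol synthesis at 0.04 (percentile 97.5, Mvd higher) and glycolysis at 0.05 (percentile 84.4, Hk2 higher).

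Set directly against M2, the M1 library had 924 of 6773 genes higher and 1196 lower, 421 and 456 of them 4-fold or more. Interferon-response genes were higher in 20 of 20 members (median 8.03, percentile 100) and classical activation genes in 13 of 16 (median 7.01, percentile 100), with Slc7a2 lower. Ly6a stood at 3477 against 0.652 CPM (5331-fold higher, 4105 to 7058) and Ccl5 at 31521 against 11.8 CPM (2661-fold higher, 2502 to 2832). Cxcl10 stood at 939 against 0.116 CPM (8062-fold higher, 4384 to 16813) and Nos2 at 338 against 0.419 CPM (805-fold higher, 582 to 1150.1). Alternative activation genes were lower in 15 of 17 members (median -5.64, percentile 0), and Il4ra, a receptor chain for IL-4, was higher, at 66.3 against 15.5 CPM (4.27-fold higher). Arg1 stood at 1.29 against 2182 CPM (1695-fold lower, 1393 to 2083), Mgl2 at 0.154 against 596 CPM (3859-fold lower) and Chil3 at 0.206 against 559 CPM (2713-fold lower). Retnla was at 0.0129 against 3579 CPM (2.78e+05-fold lower, 49900 to 1.10e+07) with 1 UMI in M1. Fn1 stood at 0.0129 against 206 CPM (15978-fold lower), also with 1 UMI in M1. Rbp4 stood at 0 UMIs against 185 CPM (at least 4803-fold lower), Mmp12 at 3.57 against 2832 CPM (794-fold lower) and Itgax at 0.798 against 215 CPM (270.01-fold lower).

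The other lists followed in the M1 against M2 comparison. MHC class II (7 of 7 higher, median 2.74, percentile 99.8), MHC class I (11 of 11, 2.62, 100) and inflammatory cytokine genes (10 of 12, 3.55, 100) were higher in M1. Lipid-associated macrophage (16 of 23 lower, median -1.86, percentile 0), resident macrophage (8 of 12, -2.44, 0), cell cycle (5 of 8, -2.22, 0) and cholesterol synthesis genes (8 of 12, -1.46, 0.010) were lower. Monocyte genes had 5 of 9 members lower, S100a4, Chil3, Fn1, F10 and Napsa, and 4 higher, Plac8, Ifitm6 and Ms4a4c among them (median -1.29, percentile 0.590). The medians were -0.28 for glycolysis (percentile 23.0), 0.13 for oxidative phosphorylation (77.2) and -0.25 for fatty acid oxidation and PPAR genes (30.7). Lysosome genes (-0.19, percentile 32.3) turned to 0.03 with TMM and 0.03 with DESeq2 factors, and immediate early and stress genes (-0.03, percentile 55.9) to 0.20 with TMM and 0.20 with DESeq2 factors. The classical minus alternative activation score per cell, at 1500 UMIs, was 0.68 higher on average in M1 than in M0 and differed by -0.38 between M2 and M0.

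**Figure D2:**
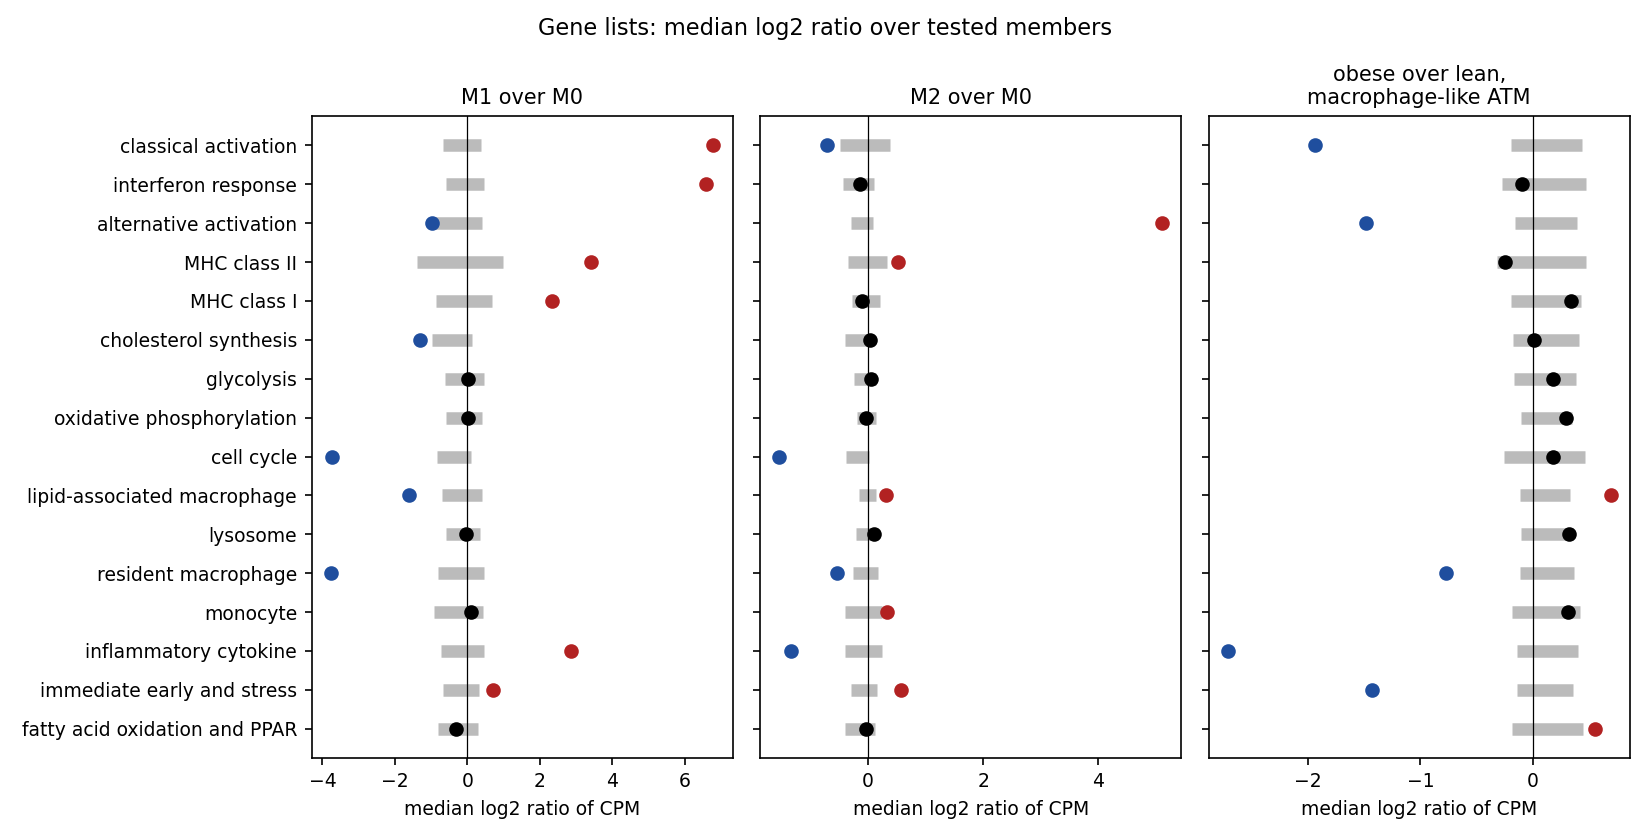
Each point is the median log2 ratio of CPM over the tested members of 1 of 16 fixed gene lists (horizontal axis, log2; lists on the vertical axis) for M1 over M0, M2 over M0 and obese over lean macrophage-like ATM, and the grey bar holds 95% of the medians of 10000 expression-matched random lists; red points lie above it, blue points below and black points within. Interferon response reaches 6.58 in M1, alternative activation 5.10 in M2, and inflammatory cytokines -2.71 in obese ATM, while under TMM or DESeq2 scaling the signs turn for lysosome and fatty acid oxidation and PPAR in the first panel, for classical activation (with 1 more member tested), interferon response, MHC class I, oxidative phosphorylation and fatty acid oxidation and PPAR in the second, and for cholesterol synthesis in the third.

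The ATM libraries were compared to ask how macrophages of obese fat differ from those of lean fat. Clusters named from fixed markers put 43.2% (Clopper-Pearson 40.9 to 45.6, 737 cells) of lean and 56.3% (54.0 to 58.6, 990 cells) of obese ATM cells in the macrophage-like class. Monocyte-like cells made up 20.1% of lean and 20.99% of obese cells, and 11.9% and 18.6% at Leiden resolution 2. Patrolling monocyte-like cells made up 11.2% (9.74 to 12.8) and 4.44% (3.52 to 5.51), and 10.97% and 8.19% at resolution 2. Conventional dendritic cells were close in share, 2.52% and 2.73% for cDC1-like and 4.69% and 5.12% for cDC2-like cells. Despite the sort, the lean library held 102 fibroblast or preadipocyte-like cells, 5.98% (4.90 to 7.22), against 0 of 1758 in obese ATM, which allows up to 0.171%. It also held 40 B cell-like cells, 2.35% (1.68 to 3.18), against 10, 0.569% (0.273 to 1.04), and a mixed endothelial and erythroid cluster of 26 cells against 0. At resolution 0.5 the B cell-like cells joined a mixed B and NK cell cluster of 57 lean and 17 obese cells.

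The sort itself and the depth, with medians of 5407 and 9838.5 UMIs per cell, can set these shares. The clusters also parted by library: macrophage-like cells lay mainly in clusters 0 (403 cells), 7 (218) and 13 (72) in lean ATM and in clusters 2 (343), 3 (324) and 5 (287) in obese ATM, so part of this structure may be the library. Clusters 0 and 3 carry the macrophage-like name by marker level alone, and with names from marker scores alone the class held 18.7% of lean and 36.3% of obese cells. That level does not set macrophages apart here. The mixed endothelial and erythroid cluster reached it too, with 9 markers at 50 CPM and a macrophage score of -1.08 against a monocyte score of -1.82. Cluster 0 had a macrophage score of -0.08 and held 403 of the 737 lean macrophage-like cells. The lean side of macrophage-like ratios therefore leans on that rule. Monocyte-like cells of lean ATM lay mainly in cluster 4 (330 cells), led by Slpi, Clec4e, Arg1, Il1b and Il6, and obese ones in cluster 1 (361 cells), led by Chil3, Plac8 and Ly6c2. Clusters 5 and 7 were called lipid-associated macrophage-like, and cluster 7 was led by the stress and chemokine genes Gdf15, Cxcl2 and Cxcl1. That name went to 13.3% of lean and 16.7% of obese cells, to 14.3% and 36.5% at resolution 0.5 and to 12.96% and 16.7% at resolution 2. An unnamed cluster led by S100a8, S100a9, Cxcl9 and Ifit1 held 37 lean and 73 obese cells, and at resolution 2 unnamed clusters held 180.0 and 5.

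**Figure D3:**
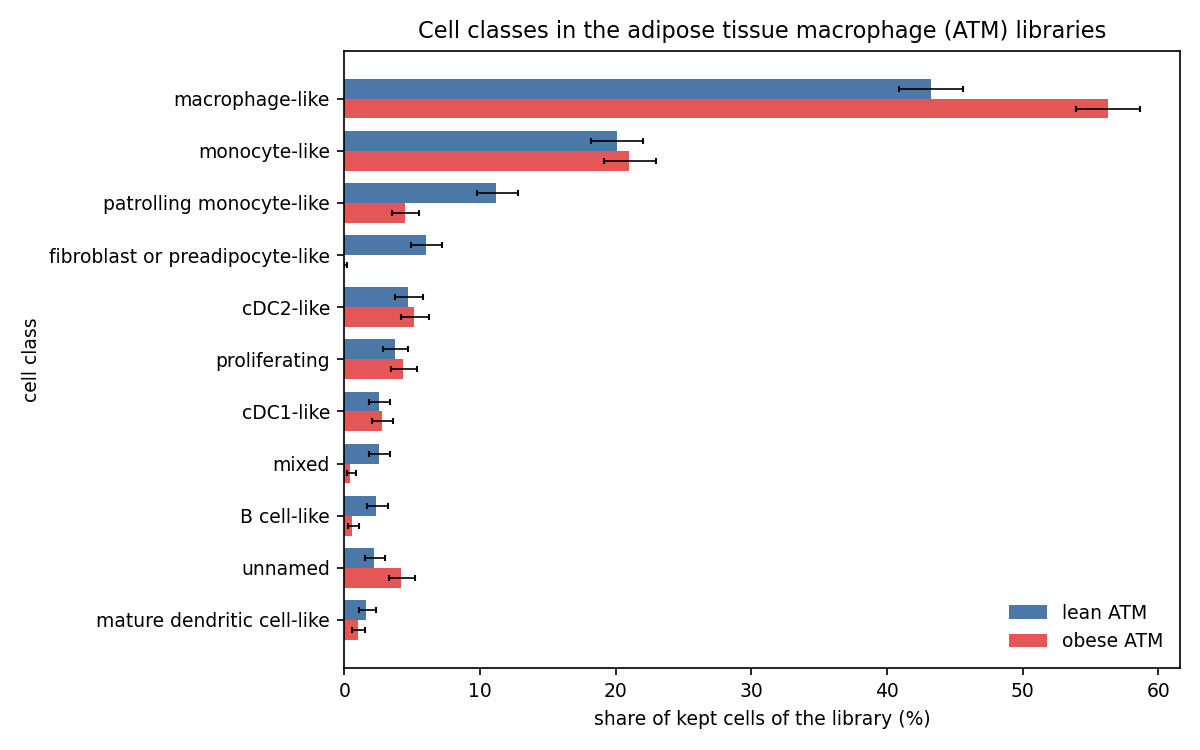
Bars give the share of kept cells (horizontal axis, percent) in each cell class (vertical axis) of the lean ATM (1705 cells) and obese ATM (1758 cells) libraries, with exact 95% Clopper-Pearson intervals that cover counting error only. Macrophage-like cells make up 43.2% of lean and 56.3% of obese cells, patrolling monocyte-like cells 11.2% and 4.44%, and fibroblast or preadipocyte-like cells 5.98% and 0%.

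Over all kept cells, obese ATM had 191 of 7862 genes higher and 612 lower than lean ATM, 13 and 303 of them 4-fold or more. List medians were higher in obese ATM for lipid-associated macrophage and lysosome genes, and lower for inflammatory cytokine, immediate early, alternative activation and resident macrophage genes. The highest ratios were those of Cpe, carboxypeptidase E (ENSMUSG00000037852, chromosome 8, 64592542 to 64693054, minus strand), at 102 against 11.8 CPM (8.58-fold higher, 7.20 to 10.3). Next came Akr1b8, an aldo-keto reductase, at 203 against 31.2 CPM (6.50-fold higher, 5.83 to 7.27), and Cd72, a C-type lectin, at 158 against 27.5 CPM (5.73-fold higher, 5.10 to 6.46). Stromal genes were among the 10 lowest in the ranking on CPM plus 1. Dcn, the matrix proteoglycan decorin (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143, plus strand), stood at 2.92 against 991 CPM (339-fold lower, 263 to 444). Others were Clec3b, at 0.487 against 211 CPM (433-fold lower), the collagen genes Col1a2, at 0.633 against 162 CPM (256-fold lower), and Col3a1, at 2.19 against 294 CPM (134-fold lower). Sult1e1, a sulfotransferase, stood at 0 UMIs against 121 CPM (at least 829.9-fold lower) and Ptx3, a pentraxin, at 0 UMIs against 91.2 CPM (at least 624-fold lower). The red-cell gene Hbb-bs stood at 1.22 against 296 CPM (243-fold lower). The lean library held fibroblast-like and mixed clusters that obese ATM lacked or held at a lower share. Without the fibroblast-like, B cell-like and mixed clusters 214 genes were higher and 352 lower (37.8% higher, against 23.8% with all cells); 334 of the 352 lower genes were also among the 612.

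Lipid-associated macrophage genes had 10 of 23 members at least 2-fold higher in obese ATM and 0 lower (median 0.92, percentile 100, random medians from -0.10 to 0.31), beside macrophage-like shares of 43.2% in lean and 56.3% in obese ATM. Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, plus strand) stood at 979 against 359.9 CPM (2.72-fold higher, 2.63 to 2.81) and Cd9, a tetraspanin (ENSMUSG00000030342, chromosome 6, 125460266 to 125494791, minus strand), at 879 against 386 CPM (2.28-fold higher, 2.20 to 2.35). Lpl, lipoprotein lipase, stood at 2927 against 1229.9 CPM (2.38-fold higher), Ctsd, cathepsin D, at 2969 against 1259 CPM (2.36-fold higher), and Atp6v0d2 at 263 against 88.6 CPM (2.97-fold higher). The lysosome list had a median of 0.43 (percentile 99.9), and the fatty acid oxidation and PPAR list 0.53 (percentile 99.8) with Cpt2 past 2-fold. Other high ratios were those of Hpgds, at 123 against 29.8 CPM (4.11-fold higher), and the ubiquitin ligase Rnf128, at 100.3 against 25.1 CPM (3.99-fold higher). They were followed by Ms4a7, at 569.95 against 149 CPM (3.83-fold higher), the adhesion molecule Cadm1, at 123 against 32.6 CPM (3.78-fold higher), Pianp, at 63.0 against 18.0 CPM (3.50-fold higher), and Ahnak2, at 65.7 against 23.3 CPM (2.81-fold higher).

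On the lower side all 15 tested inflammatory cytokine genes were lower in obese ATM (median -2.59, percentile 0), as were 14 of 17 immediate early and stress genes (median -1.41, percentile 0) and 10 of 14 classical activation genes (median -1.87, percentile 0). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139, minus strand) stood at 69.6 against 289 CPM (4.15-fold lower, 3.90 to 4.42) and Il6 at 0.244 against 26.8 CPM (110.04-fold lower). Ccl2 stood at 53.7 against 456 CPM (8.49-fold lower) and Cxcl2, a neutrophil chemokine, at 436 against 3074 CPM (7.05-fold lower). At 1500 UMIs an Il1b UMI was seen in 24.9% of lean and 7.57% of obese cells, and in 7.50% of lean B cell-like cells (median 4030 UMIs before thinning). Alternative activation genes were lower in 9 of 15 members (median -1.66, percentile 0). Retnla stood at 632 against 8384 CPM (13.3-fold lower, 13.03 to 13.5) and Ccl17 at 5.07 against 109.9 CPM (21.7-fold lower). Ccl24 stood at 33.4 against 225 CPM (6.74-fold lower) and Arg1 at 8.92 against 45.2 CPM (5.06-fold lower). Of 18 resident macrophage genes 8 were lower and Folr2, at 341 against 169.9 CPM (2.01-fold higher), higher (median -0.42, percentile 0). Cd209f, a C-type lectin (ENSMUSG00000051906, chromosome 8, 4102787 to 4105835, minus strand), stood at 0.780 against 66.1 CPM (84.8-fold lower, 51.9 to 149). Lyve1, the hyaluronan receptor (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239, minus strand), stood at 0.780 against 30.9 CPM (39.6-fold lower, 24.1 to 70.1). Both mark cluster 13, called resident macrophage-like, which held 72 lean cells (4.22%) and 1 obese cell. That name went to more cells at other resolutions: 28.0% of lean and 1.65% of obese cells at 0.5, and 12.8% and 0.284% at 2.

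Interferon-response genes had a median of 0.27 (percentile 89.7), with Isg15, Irf1 and Ly6a past 2-fold lower, and Ly6a at 13.2 against 153 CPM (11.6-fold lower). MHC class I stood at 0.23 (percentile 78.2), oxidative phosphorylation at 0.28 (94.1), cell cycle at 0.27 (91.5) and glycolysis at 0.12 (51.7, Hk2 lower). The cell cycle median turned to -0.08 with a floor of 50 CPM. The monocyte list stood at 0.01 (23.4), with Vcan and Fn1 lower, and cholesterol synthesis at -0.13 (7.56), with Insig1 among the lower members and Dhcr7 higher. The MHC class II median of -0.01 (29.6) had no firm sign, at -0.00099 with TMM and 0.0028 with DESeq2 factors. Cd74 stood at 21918 against 22368 CPM.

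Within macrophage-like cells, held mainly by clusters 2, 3 and 5 in obese and 0, 7 and 13 in lean ATM, 221 of 7461 genes were higher in obese ATM and 409 lower, 26 and 114 of them 4-fold or more. The counts were 393 and 602 by the mean of per-cell CPM, 67 and 178 with a floor of 50 CPM and 816 and 1367 with no floor. List medians were lower for inflammatory cytokine, immediate early, alternative activation and resident macrophage genes and higher for lipid-associated macrophage genes, the directions of the all-cell comparison. Ccl4, a chemokine (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683, plus strand), stood at 92.4 against 829 CPM (8.98-fold lower, 8.43 to 9.57). Egr1, an immediate early transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, plus strand), stood at 35.0 against 375 CPM (10.7-fold lower, 9.69 to 11.9) and Trem2 at 1323 against 635 CPM (2.08-fold higher, 2.01 to 2.16). Retnla stood at 869 against 14219 CPM (16.4-fold lower, 16.1 to 16.7). Retnla, Fn1 and Mgl2 lead cluster 0 and Cxcl2 and Ccl24 are among the leading genes of cluster 7, both made up mostly of lean cells. Cluster 0 is macrophage-like by marker level alone, a level that the mixed endothelial and erythroid cluster also reached. Over all cells Mgl2 stood at 87.5 against 289 CPM (3.30-fold lower) and Fn1 at 198 against 607 CPM (3.07-fold lower).

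All 14 tested inflammatory cytokine genes were lower in obese macrophage-like cells (median -2.71, percentile 0). Cxcl2 stood at 561 against 4663 CPM (8.30-fold lower, 8.09 to 8.52) and Tnf at 52.9 against 214 CPM (4.03-fold lower, 3.67 to 4.44). Nfkbia, an inhibitor of NF-kappaB, was at 412 against 1638 CPM (3.97-fold lower), Ccl2 at 61.0 against 372 CPM (6.11-fold lower) and Il6 at 0.0751 against 12.6 CPM (168-fold lower, 29.1 to 6717), with 1 UMI in obese cells. Classical activation genes were lower in 9 of 12 members (median -1.94, percentile 0). Immediate early and stress genes were lower in 14 of 17 members (median -1.43, percentile 0, random medians from -0.14 to 0.36). Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand) stood at 1062 against 2719.6 CPM (2.56-fold lower, 2.50 to 2.62). The related Fosb was at 52.0 against 379.7 CPM (7.30-fold lower), Junb at 919.6 against 2476 CPM (2.69-fold lower) and Hspa1a, a heat-shock protein, at 79.2 against 484 CPM (6.11-fold lower). A Fos UMI was seen at 1500 UMIs in 90.8% of lean and 60.5% of obese macrophage-like cells, and in 52.5% of lean and 3 of 10 obese B cell-like cells. Hspb1, a small heat-shock protein, stood at 2.25 against 61.8 CPM (27.4-fold lower) and Cxcl10 at 11.2 against 106 CPM (9.50-fold lower).

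Alternative activation genes were lower in 8 of 14 members (median -1.48, percentile 0), and Chil3 was higher, at 59.9 against 13.9 CPM (4.32-fold higher, 3.40 to 5.55). Chil3 leads the obese monocyte-like cluster 1, and with names from marker scores alone its log2 ratio was -0.04. Mgl2 stood at 83.5 against 359 CPM (4.30-fold lower, 3.99 to 4.63), Ccl24 at 40.7 against 354 CPM (8.69-fold lower), Ccl17 at 1.502 against 39.2 CPM (26.1-fold lower), and Mrc1 at 212 against 301 CPM (1.42-fold lower, 1.33 to 1.51). Resident macrophage genes were lower in 9 of 18 members (median -0.77, percentile 0), with Cd209f at 1.13 against 114 CPM (101-fold lower), Lyve1 at 0.976 against 52.6 CPM (53.9-fold lower) and Cd163, a haemoglobin scavenger receptor, at 13.7 against 60.3 CPM (4.39-fold lower). Monocyte genes had 5 of 11 members higher, Ly6c2, Plac8, Chil3, Hp and Ms4a4c, and Fn1 lower (median 0.31, percentile 85.6). This median had no firm sign, at -0.04 with every deposited barcode, -0.02 without the 5% of cells with the highest Scrublet scores and -0.65 with names from marker scores alone. Fn1 stood at 172 against 709.5 CPM (4.13-fold lower). Plac8 stood at 438 against 115 CPM (3.82-fold higher) and turned to a log2 ratio of -0.06 with names from marker scores alone. Dcn stood at 3.08 against 61.8 CPM (20.1-fold lower). Its lean level is that of free RNA, since lean B cell-like cells held 62.1 and cDC1-like cells 45.3 CPM, against 13970 CPM in fibroblast or preadipocyte-like cells.

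Lipid-associated macrophage genes had 5 of 23 members at least 2-fold higher, Trem2, Cd9, Lipa, Ctsk and Atp6v0d2, and 0 lower (median 0.69, percentile 100, random medians from -0.12 to 0.33). Cd9 stood at 1135 against 434 CPM (2.62-fold higher, 2.51 to 2.74), Ctsk at 336 against 111 CPM (3.03-fold higher), Lipa, the lysosomal acid lipase, at 826 against 402 CPM (2.06-fold higher), and Ctsb, cathepsin B, at 8510.2 against 4637 CPM (1.84-fold higher). The fatty acid oxidation and PPAR list stood at 0.55 (percentile 99.8), with Hadha, of mitochondrial beta-oxidation, at 133 against 74.2 CPM (1.79-fold higher), and the lysosome list at 0.32 (94.8). The highest ratios of single genes were those of Cpe, at 143 against 12.6 CPM (11.4-fold higher, 8.94 to 14.7), Zranb3, at 57.4 against 6.66 CPM (8.62-fold higher), and Serpinb6b, at 67.0 against 9.07 CPM (7.39-fold higher). Akr1b8 stood at 284 against 51.1 CPM (5.57-fold higher) and Mfge8, a bridge to dying cells, at 112 against 20.0 CPM (5.597-fold higher). The transcription factor Sox4 was at 61.6 against 11.7 CPM (5.28-fold higher) and Cd72 at 201 against 43.9 CPM (4.57-fold higher). Cpe, Akr1b8 and Zranb3 lead cluster 5.

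The remaining medians in macrophage-like cells were -0.09 for interferon response (percentile 10.8, with Isg15, Rsad2, Irf1 and Ly6a lower) and -0.25 for MHC class II (4.96), which was 0.08 with names from marker scores alone. They were 0.34 for MHC class I (89.9), 0.18 for glycolysis (65.8), 0.29 for oxidative phosphorylation (91.1) and 0.18 for cell cycle (58.6). With no floor the cell cycle median turned to -0.08 and that of interferon response to 0.17. Cholesterol synthesis stood at 0.01 (20.7) and turned to -0.06 with TMM and -0.04 with DESeq2 factors. With TMM or DESeq2 factors the median of all tested genes moved by -0.07 or -0.05.

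**Figure D4:**
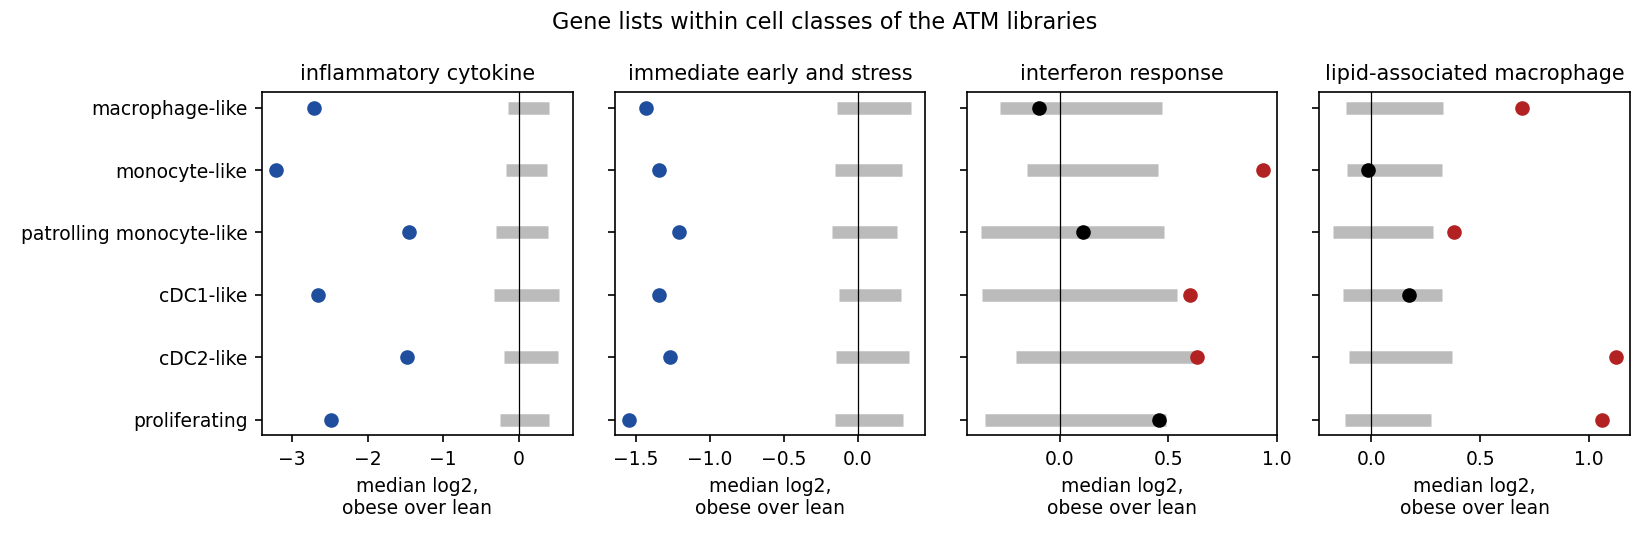
Each point is the median log2 ratio, obese over lean ATM (horizontal axis, log2), of 1 of 4 gene lists within each of 6 cell classes (vertical axis), and the grey bar holds 95% of the medians of 10000 expression-matched random lists; red points lie above it, blue points below and black points within. Immediate early and stress genes are lower in obese cells of every class shown, from -1.55 in proliferating to -1.21 in patrolling monocyte-like cells, while interferon response reaches 0.94 in monocyte-like cells and lies at -0.09 in macrophage-like cells.

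Signatures taken from the BMDM libraries were read in the ATM libraries to ask whether M1 or M2 genes differ with obesity. Every M1 signature gene was at least 12.3-fold higher in M1 than in M0 and M2, and every M2 signature gene at least 1.89-fold higher in M2. In macrophage-like cells the 93 measured M1 signature genes had a median log2 obese over lean ratio of 0.19 (counting interval 0.08 to 0.37), at percentile 92.1 of random lists, with 17 members at least 2-fold higher and 16 lower. This median moved to -0.00063 with names from marker scores alone, and its percentile ran from 6.96 to 98.8 over the alternatives. The 98 measured M2 signature genes had a median of -0.15 (-0.30 to -0.13), at percentile 0 of random lists (random medians from 0.02 to 0.26), with 4 members higher, Chil3, Dhrs9, Mfge8 and Atp6v0d2, and 19 lower, Retnla, Mgl2 and Ccl24 among them. The classical minus alternative activation score was 0.06 higher on average in obese than in lean ATM cells, and it differed by -0.05 without the member of each list with the highest CPM, so it has no firm sign.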

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

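The tests of a response of macrophage-like cells alone, of free RNA in classes other than B cell-like cells, of macrophage-like RNA in other cells, of resident macrophage-like cells at Leiden resolutions 0.5 and 2, of a difference between the libraries in M2 genes and of macrophage markers per fibroblast-like cell were chosen only after the result was seen; the other tests were written down before their result. No test compares animals, since each group is 1 library, and the difference in diet therefore stays open and untested throughout.

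Signal also appeared in barcodes outside the kept cells. The 5 lean ATM barcodes left out for few detected genes held 12479 UMIs, of which 95.1% came from haemoglobin genes: Hbb-bs made up 44.6%, Hba-a1 26.1%, Hba-a2 19.3% and Hbb-bt 5.11%. In the kept lean cells Hbb-bs made up 0.0296% of UMIs.

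Immediate early and cytokine genes, which respond within minutes to hours to digestion and sorting as well as to inflammation, were higher in lean than in obese ATM. Every test below used the immediate early and stress list, so none of the verdicts covers the cytokine list. A response of macrophage-like cells alone is argued against by the other classes. The highest median log2 obese over lean ratio of the list among monocyte-like, patrolling monocyte-like, cDC1-like and cDC2-like cells was -1.21 (counting interval -1.33 to -1.05). Without macrophage-like RNA at the level that Retnla sets, these classes held the list at 1.87 (1.77 to 1.96) times the obese CPM or more. With the higher ratio of list to Retnla of cluster 7 they held it at 1.04 (0.935 to 1.13), in patrolling monocyte-like, to 1.53 (1.45 to 1.61) times, in cDC2-like cells. Outside monocyte-like cells this verdict assumes that Retnla tracks macrophage-like RNA, because the limits below that do not use Retnla leave free RNA open there. Handling that acted on every cell of the lean library stays open as a candidate explanation, since in B cell-like cells, 40 lean and 10 obese, the median over 17 members was -1.92 (-2.25 to -1.45); a diet effect on every cell type would look alike. Free RNA as the source of all list RNA is argued against in macrophage-like, monocyte-like and cDC2-like cells, as far as counting error goes. They held 1.57 times or more of the list in lean B cell-like cells, 9748 CPM and 43.2 UMIs per cell, though these were taken as all free. In the 43 lean cDC1-like cells the ratio was 1.18 (1.12 to 1.25) by CPM and 2.46 by UMIs per cell. The interval holds no spread between cells, so no verdict is drawn for cDC1-like cells. The spread of the 40 B cell-like cells is missing from every such ratio. Free RNA at the level of Retnla, 13.9% of the library's, would bring 2115 CPM of the list. B cell-like cells held 4.61 times that level, and the 5 other classes 5.44 (4.75 to 6.27) times or more. That reading assumes the library's average make-up. Free RNA as the cause of the lean excess is argued against in monocyte-like cells, as far as counting error goes. There 1.18 (1.10 to 1.26) times the obese CPM was left without the B cell-like CPM. Without the B cell-like UMIs per cell 1.51 times was left. The level taken off rests on 40 B cell-like cells, whose spread is not in the interval. Monocyte-like cells lay mainly in cluster 4 in lean ATM (330 cells) and in cluster 1 in obese ATM (361 cells). These ratios therefore also compare those clusters. Free RNA cannot be told apart from expression in B cell-like cells and in the other 4 classes. In these 4 classes 0.335 (0.231 to 0.448) times, in cDC1-like, to 0.939 times, in macrophage-like cells, was left by CPM. By UMIs per cell -0.217 times, in patrolling monocyte-like, to 1.59 times, in macrophage-like cells, was left.

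Fibroblast or preadipocyte-like cells, 102 in lean ATM and 0 in obese ATM, were found behind a sort for CD45.2, CD11b and F4/80. Doublets of a fibroblast and a macrophage could explain their passage: the 11 macrophage markers summed in them to 5333 CPM, 29.4% of the 18139 CPM in lean macrophage-like cells, above the bound of 25% set for doublets beforehand. That sum leans on a few genes, since single markers ranged from 12.6% to 74.3% and the sum without Apoe was 21.9%. Cell by cell, 21.6% (Clopper-Pearson 14.0 to 30.8; 22 of 102) held the markers other than Apoe at 25% or more of the macrophage-like median, against 84.0% of macrophage-like and 10.0% (4 of 40) of B cell-like cells, so whether doublets make up most of this cluster cannot be told apart from sorted stromal cells that carry free RNA. The median depth of 6994 UMIs, beside 6168 in macrophage-like cells, does not decide it, and a true difference in stromal cells between lean and obese fat was not tested.

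The M2 signature was lower in obese than in lean macrophage-like cells, at a median log2 ratio of -0.15. Loss of the resident macrophage-like cells is argued against as the whole cause, because without the 72 lean and 1 obese cells of that name the median was -0.17 (-0.27 to -0.12). The name went to 478 and 29 cells at Leiden resolution 0.5 and to 218 and 5 at 2, and without these the medians were -0.22 (-0.33 to -0.17) and -0.18 (-0.31 to -0.13). The cells left were still split by library. At resolution 1 they included cluster 0, with 403 lean and 28 obese cells. At 0.5 they included a cluster of 217 lean and 7 obese cells with Ccl24 among its leading genes. The medians therefore also compare clusters. A difference between the libraries in every cell type cannot be told apart from one in macrophage-like cells: the M2 signature medians were -0.28 in monocyte-like, -0.0042 in patrolling monocyte-like, -0.08 in cDC1-like and 0.17 in cDC2-like cells, the highest of the 4, with no interval on any of them. Diet and library are the same split here.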

How the results depend on the processing

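The alternatives chosen after seeing the data were removal of the 5% of cells with the highest Scrublet scores, the ATM comparison without fibroblast-like, B cell-like and mixed clusters, macrophage-like cells named by marker score alone, and all those of the ATM activation score. Of 166 values that answer a comparison under an alternative, 114 stayed close to the main value: 95 under those set beforehand and 19 under added alternatives. Close had a separate rule for each kind of value. A gene count could change up to a fixed bound under 2-fold, and a score had to match to 2 decimals. Shares, signature and list medians and single genes had to stay inside the counting interval of the main value. The tally is therefore not a single measure. Alternatives set beforehand moved 43 without turning any, and added ones moved 7 and turned 2. Of 5718 values for single genes and lists, 3975 stayed close, 1737 moved and 6 turned, where turned means a change of sign by a gene past 2-fold or by a list median outside the range of random lists. Among the values counted as close or moved, 44 of lists inside that range and 46 of genes under 2-fold also changed sign. No paired analysis was possible because each group holds 1 library, and no replicate could be left out for the same reason. Depth limits the lean ATM library most, with a median of 5407 UMIs per cell, and intervals cover counting error only.

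Scaling gave 1126 higher and 827 lower genes for M1 over M0 with TMM and 1190.0 and 773 with DESeq2 factors. A floor of 50 CPM, which tests fewer genes, gave 434 higher and 461 lower for M1 over M0, 123 and 81 for M2 over M0, 501 and 525 for M1 over M2, 79 and 214 for obese over lean over all cells, and 67 and 178 over macrophage-like cells. No floor, which admits genes of few counts, gave 1585 and 4245, 1092 and 1543, 1964 and 3708, 658 and 2727, and 816 and 1367. Without fibroblast-like, B cell-like and mixed clusters 352 genes were lower over all cells, and the mean of per-cell CPM gave 393 higher genes over macrophage-like cells.

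The values that turned were the alternative activation list for M1 over M0, at 1.65 with a floor of 50 CPM, the classical activation list for M2 over M0, at 0.15 with TMM and 0.16 with DESeq2 factors, and the monocyte list for M2 over M0, at -0.75 with no floor. With names by marker score alone, Chil3 turned to -0.0382 and Plac8 to -0.0625 in macrophage-like cells, and the M1 signature to -0.00063. For classical activation the turn came from testing 5 members in place of 4, since the same 4 stood at -0.55 with TMM and -0.54 with DESeq2 factors. For the others the cause was not tested. List medians inside the random range that changed sign with DESeq2 factors were lysosome and fatty acid oxidation and PPAR for M1 over M0, interferon response, MHC class I, oxidative phosphorylation and fatty acid oxidation and PPAR for M2 over M0, lysosome and immediate early and stress for M1 over M2, MHC class II over all ATM cells and cholesterol synthesis in macrophage-like cells. TMM factors changed the sign of the same lists other than MHC class II. Under other alternatives glycolysis and monocyte genes for M1 over M0, cell cycle over all ATM cells, and interferon response, MHC class II, cell cycle and monocyte genes in macrophage-like cells changed sign.

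The macrophage-like share of lean ATM was 47.7% with every barcode, 48.2% with stricter filters, 49.7% without the highest Scrublet scores and 18.7% by marker score alone, where the obese share was 36.3%. The cause was not tested. The M1 signature stood at 0.0028 with genes of at least 10 CPM, and its percentile among random lists ran from 6.96 there to 98.8 at resolution 2. The M2 signature stood at -0.44 with 50 genes, -0.079 with 200 genes, -0.13 with genes of at least 10 CPM and -0.31 by marker score alone, at percentile 0 in each.

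Depth set the shares of cells with a UMI. Nos2 was seen in 25.7% of M1 cells at 1000 UMIs, 55.3% at 3000 and 89.9% unthinned, and Arg1 in 68.8%, 87.2% and 97.7% of M2 cells. The classical minus alternative score differed between M1 and M0 by 0.62 at 1000 UMIs, 0.77 at 3000 and 0.45 without the member with the highest CPM, and between M2 and M0 by -0.34, -0.43 and -0.29. Between obese and lean ATM it differed by 0.06, by 0.0748 at 1000 UMIs and 0.0696 at 3000, and it turned to -0.0534 without that member, for which the cause was not tested.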

Other observations

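Every value in this part was looked up after the main comparisons had been seen, and none has a replicate check. Fold values of lists are medians over tested members and can lie under the 2-fold rule. Members past that rule are not counted by class here. Interferon-response genes, close to even in macrophage-like cells, had higher medians in obese ATM in several other classes. In monocyte-like cells the list's median was 1.92-fold higher, at percentile 100 of random lists, in cDC1-like cells 1.52-fold higher (percentile 98.7), in cDC2-like cells 1.55-fold higher (percentile 97.6) and in proliferating cells 1.37-fold higher (percentile 96.6). In patrolling monocyte-like cells it was 1.08-fold higher (percentile 57.8). The list's median lay within the range of 95% of random lists in proliferating and patrolling monocyte-like cells. In cDC2-like cells it lay only just above that range, at log2 0.632 against 0.628. The MHC class I median lay above the range of 95% of random lists in monocyte-like (1.34-fold, percentile 98.6), cDC1-like (1.29-fold, 99.25) and proliferating cells (1.395-fold, 99.5). It lay within that range in cDC2-like (1.29-fold, 95.8), macrophage-like (1.26-fold, 89.9) and patrolling monocyte-like cells (0.899-fold, 8.74). The cholesterol synthesis median was 1.75-fold lower in obese ATM in monocyte-like cells (14 members, percentile 0). In patrolling monocyte-like cells it was 1.79-fold lower (10 members, percentile 0.160). It stood at 0.892-fold in cDC1-like cells (percentile 17.2) and was 1.28-fold higher in cDC2-like (percentile 73.7) and 1.12-fold higher in proliferating cells (percentile 67.5). Most monocyte-like cells lay in cluster 4 in lean ATM and in cluster 1 in obese ATM, so these values also compare those clusters.

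The lipid-associated macrophage list also had higher medians in obese ATM in some other classes. They were 2.18-fold in cDC2-like cells (percentile 100), 2.08-fold in proliferating cells (100) and 1.301-fold in patrolling monocyte-like cells (99.8). Against these stood 1.13-fold in cDC1-like (75.4) and 0.990-fold in monocyte-like cells (11.9). Proliferating cells were not set apart from macrophages. Their cluster 9 (117 cells) had a macrophage score of 0.20 and lipid-associated macrophage as its second class. Lean proliferating cells held Retnla at 9682 CPM, against 1162 CPM in lean B cell-like cells. The lysosome median was 1.70-fold higher in cDC2-like (percentile 100) and 1.52-fold higher in proliferating cells (99.99). It was 1.23-fold in cDC1-like (94.9), 1.19-fold in monocyte-like (91.3) and 1.08-fold in patrolling monocyte-like cells (65.9). These classes hold 80 and 90 (cDC2-like) and 63 and 76 (proliferating) lean and obese cells. Free RNA from macrophage-like cells can reach every class, and its share in this difference was not measured. Inflammatory cytokine genes were lower in obese ATM by a median of 9.22-fold in monocyte-like cells, 6.29-fold in cDC1-like cells, 5.61-fold in proliferating cells, 2.78-fold in cDC2-like cells and 2.74-fold in patrolling monocyte-like cells, at percentile 0 in each.

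The cultured libraries were not uniform. In M0 a cluster of 43 cells, 0.626% (0.453 to 0.842) of the library, was led by the interferon-response genes Rsad2, Ifit3 and Ifit1 without added interferon, and a cluster of 286 cells, 4.16%, by the MHC class II genes H2-Aa and Cd74. In M1 a cluster of 351 cells, 7.70% (6.94 to 8.51), was led by Ccr7, Il12b and Il4i1, and a cluster of 1151 cells, 25.2%, by Ccl3 and Ccl7, with Ccl4 also among its leading genes. Ccl3 and Ccl4 were lower in the M1 library as a whole than in M0. In M2 a cluster of 645 cells, 10.3%, was led by H2-Aa and H2-Eb1, with Ccl17, Ccl24 and Ccl22 among its leading genes. An M1 cluster of 83 cells, 1.82%, led by mitochondrial genes, had a median of 7.64% mitochondrial UMIs, close to the filter of 10%.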
